A study of Homo sapiens with 12 samples.

How the data were processed

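The data are one table of whole-number gene counts for 12 RNA sequencing libraries, deposited by the authors as raw counts. HISAT2 2.0.4 is named in the submitters' processing notes. The counting program, its treatment of strand, the genome build and the annotation are not given in the sources used here, so antisense and overlapping genes cannot be told apart and no coordinates are given. The table has 54261 genes, of which 29822 had at least 1 count. Of the 15591 gene names tested, 13920 matched a current RefSeq symbol and 14754 a symbol or synonym. RPS18 and TAP1, genes of the major histocompatibility region, had 0 counts in all 12 libraries, so levels of genes in that region, DPCR1 among those named, are uncertain.

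Libraries were grouped by their titles, 3 in each of 4 groups, and matched to columns by the short names in their records. These short names begin with LR for the libraries titled K562R, which would fit LAMA84-R better, and the sources used here do not spell them out. Total counts per library set the precision. A floor of 3 counts per library stands for what a count of 0 allows, and floors cover counting error only. Counts were scaled with edgeR 4.0.16 (TMM) in R 4.3.3 after filterByExpr over the 4 groups. One quasi-likelihood fit with robust dispersions over all 12 libraries had a mean per group (8 residual degrees of freedom), and all tests were two-sided with Benjamini-Hochberg adjustment at 0.05. The contrasts were siANGPT1 against empty vector in each set, the difference of those 2, and the empty vector sets against each other. CPM values are TMM-scaled. Because one spread is shared by both sets, a library that stands apart in one set can change the calls in the other.

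The comparisons, alternatives, 31 gene lists and the rule for named genes were set before the data were examined. The rule took ANGPT1, the 10 genes with the largest rise and the 10 with the largest fall in each knockdown and between the empty vector sets, among those past the threshold with a mean of at least 5 CPM, no overlap between groups and a symbol that is not a clone or locus identifier, 5 genes per direction for both sets together and for the difference, up to 4 called members per list, and 10 genes of the pathway (JAK2, STAT5A, STAT5B, TEK, TIE1, CISH, SOCS2, PIM1, BCL2L1, MYC). By chance, 10% of genes would show no overlap between groups of 3. ATF3, ASNS, DDIT3, TXNIP, HDC, MANF, HBE1, CA1, IDI1, AQP1, CREB3L1, GALC and PTMS were named after their values were seen. So were those genes named only in the last part of the document that the rule did not take, SMARCB1, TRAPPC4 and TBCE among them. Lists were tested with limma 3.58.1 by camera on log2 CPM (prior count 2) with a preset correlation of 0.01, again with an estimated correlation, and by fry, each adjusted over the lists of a contrast. Fry was run in a directional form and in a mixed form, which counts changes either way. Its results given here are directional unless called mixed.

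Alternatives were the size factors of DESeq2, library size alone, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, a replicate block, each set of 6 libraries alone, a minimum log2 fold change of 1, and leaving out each library in turn. No pair of libraries in a group agreed within sampling noise (chi-square per degree of freedom 1.94 to 80.4).

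The tests were tried on counts simulated from the real means, library sizes and dispersions, with known changes planted in 5 draws. For the comparison labelled K562R, edgeR recovered 34.3% of genes changed 1.5-fold, 62.4% of those changed 2-fold and 85.8% of those changed 4-fold, and 4.56% of its calls were false. For the comparison labelled LAMA84-R these were 37.3%, 66.9% and 93.3%, with 6.68% false. False calls made up 12.0% and 16.4% with DESeq2 and 3.23% and 11.5% with limma voom. Camera found a planted list in all 5 draws and called 0 of 150 random lists. The planted list held only genes raised 1.5-fold to 4-fold, so it does not show whether camera finds smaller shifts. The simulated genes were drawn independently of each other, and no library was made to stand apart. Few false list calls were therefore likely in advance, and these rates need not hold for the real data, whose list genes can be correlated. A test of an exchange of the line names, written before the result was seen, is not reported here because it rests on an item withheld for evaluation.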

Results

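Messenger RNA levels were measured by RNA sequencing in what the labels name as 2 chronic myeloid leukaemia lines resistant to tyrosine kinase inhibitors (TKI), K562R and LAMA84-R. K562 and LAMA84 are established human lines that carry the BCR-ABL1 fusion. By the labels, each line had been given either an empty vector or a lentiviral construct against ANGPT1 (siANGPT1). With an empty vector as the only control, other effects of the construct cannot be told apart from the loss of ANGPT1. The design text of the series speaks instead of bone marrow cells of patients, a conflict that is not settled here, and the labels were followed. ANGPT1 is angiopoietin-1, a secreted ligand of the receptor TEK, and the series title links it to JAK/STAT5 signalling and TKI resistance. There were 3 libraries in each of 4 groups, 12 in all. Total counts ran from 12765607 to 16163614 in the libraries labelled K562R and from 17159915 to 22713381 in those labelled LAMA84-R. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

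The line names were checked first with MTAP, a 9p21 gene that the K562 line lacks by deletion. MTAP had 1203 to 1435 counts in each of the 6 libraries labelled K562R. It had 0 counts in all 6 labelled LAMA84-R, which allows up to 0.162 CPM (3 counts) in the shallowest of them. The short names that the records of these libraries carry begin with LR for those titled K562R, which would fit LAMA84-R. The short names of the others name no line. MTAP goes against the line names, so the libraries are called labelled K562R and labelled LAMA84-R throughout, the groups follow the titles, and every direction drawn between the sets depends on those titles. CDKN2A, the neighbouring 9p21 gene, had 0 or 1 count in each library labelled K562R and 2 to 24 in each labelled LAMA84-R. It was at no more than 1.01 CPM in any library. CDKN2B, also of 9p21, had 0 to 2 counts in the libraries labelled K562R and 1 to 7 in the others.

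ANGPT1, the targeted gene, fell from 209.9 ± 4.97 to 62.8 ± 3.55 CPM (SD, n = 3 each) in the libraries labelled K562R. Its log2 fold change was -1.74 (SE 0.0850, edgeR adjusted p = 4.86e-07), and all 3 siANGPT1 libraries lay below all 3 controls. In the libraries labelled LAMA84-R it was 124.8 ± 6.13 CPM with empty vector and 99.3 ± 10.5 CPM with siANGPT1 (SD, n = 3 each). That log2 fold change of -0.33 (SE 0.0819) did not pass the threshold (edgeR adjusted p = 0.0679), although all 3 siANGPT1 libraries again lay below the controls. It passed without replicate 1 of the siANGPT1 libraries (-0.27, adjusted p = 0.0235), without replicate 2 (-0.42, adjusted p = 0.0178) and with DESeq2 (-0.32, adjusted p = 0.0122), and the adjusted p over all settings ran from 0.0122 to 0.422. The log2 fold changes of the 2 sets differed by -1.41 (SE 0.117, edgeR adjusted p = 8.09e-05).

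**Figure D1:**
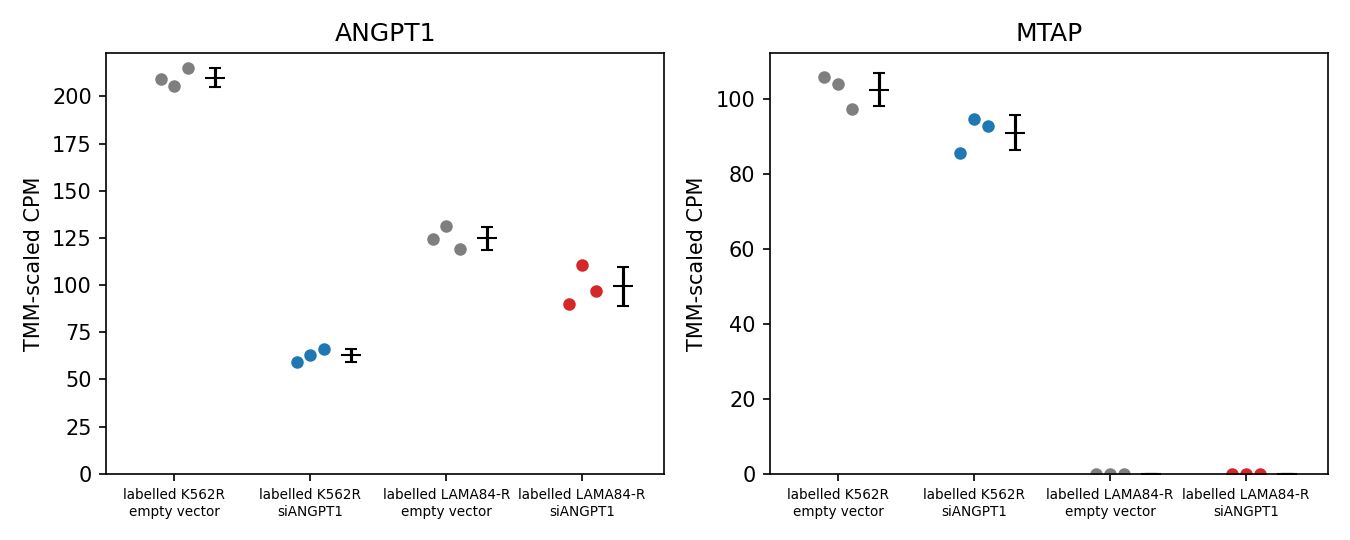
TMM-scaled CPM of ANGPT1 and MTAP in each library (points), with the mean and SD of each group of 3 (bars). ANGPT1 lies between 59.2 and 66.3 CPM in the siANGPT1 libraries labelled K562R and between 90.1 and 110.8 CPM in those labelled LAMA84-R, and MTAP is at 0 in all 6 libraries labelled LAMA84-R.

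In the libraries labelled K562R, MYEF2 rose with siANGPT1 from 1.84 ± 0.523 to 12.7 ± 1.99 CPM and RYR3, a ryanodine receptor calcium channel, from 3.64 ± 0.882 to 23.3 ± 2.76 CPM (SD, n = 3 each). The ephrin receptor gene EPHA5 (log2 fold change 2.65), the sestrin gene SESN3 (2.41) and NNMT (1.64), nicotinamide N-methyltransferase, rose too. The extracellular matrix gene HMCN1 fell from 33.6 ± 1.95 to 5.31 ± 0.838 CPM, and BMP6, a ligand of the BMP family, fell from 76.6 ± 1.28 to 17.1 ± 0.669 CPM (SD, n = 3 each). The BMP and activin receptor gene ACVR1 (-1.66), the myosin gene MYO10 (-1.61) and CD84 (-1.53) also fell. GNG12, ZDHHC23, LRP11, TMEM170B and IKZF2 rose with log2 fold changes of 1.56 to 1.80, and FRY, MPP7, ZNF648 and MGAT3 fell with log2 fold changes of -2.13 to -1.46. Of these 20 genes, ANGPT1 among them, 18 passed whichever library was left out. In this set, TMEM170B did not pass without any 1 of the 3 controls or siANGPT1 replicate 2 or 3 (adjusted p up to 0.0952), nor ZNF648 without control replicate 3 (adjusted p = 0.0574).

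In all, 485 genes were higher and 398 lower in the siANGPT1 libraries labelled K562R, of 15591 tested (edgeR, adjusted p under 0.05), and scaled by library size alone 681 and 302. With an absolute log2 fold change of at least 1 there were 215 and 56. The test shares its spread between both sets, and replicate 1 of the siANGPT1 libraries labelled LAMA84-R stood apart. Without that library 1624 genes were higher and 1668 lower, with only the 6 libraries labelled K562R 1919 and 2080, and without any 1 of these 6 between 373 and 450 in all.

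Of 38 ATF4 and unfolded protein response genes, 5 fell in the libraries labelled K562R and 33 did not pass (adjusted over the list alone, 6 fell; camera adjusted p = 0.000158). The endoplasmic reticulum chaperone genes CALR (-0.78), CANX (-0.33), SDF2L1 (-0.62) and PDIA4 (-0.48) were among them, with MANF (-0.48). Of 33 G1/S replication genes, 2 fell (adjusted over the list alone, 9 fell and 1 rose; camera adjusted p = 0.000712), the helicase subunit gene MCM3 (-0.51) and the histone chaperone gene CHAF1A (-0.26). Of 11 basophil and mast cell genes, 3 fell (adjusted over the list alone, 4; camera adjusted p = 0.0172): the IgE receptor gene FCER1A (-1.33), the stem cell factor receptor gene KIT (-0.75) and TPSAB1 (-1.84), which is uncertain because near-identical tryptase genes can share its reads. Of 30 erythroid genes, 4 fell and 2 rose (adjusted over the list alone, 8 and 4; camera adjusted p = 0.0235). The transferrin receptor gene TFRC fell from 1269.8 ± 39.5 to 801 ± 62.1 CPM (SD, n = 3 each), with RHAG (-0.38), ALAS2 (-1.69) and NFE2 (-0.35), while the embryonic globin gene HBE1 (0.79) and the carbonic anhydrase gene CA1 (1.13) rose. Of 13 mitochondrially encoded genes, 1 rose, ND3 (0.36) (adjusted over the list alone, 3; camera adjusted p = 0.0176). None of these 5 list calls held with an estimated correlation, where the adjusted p was 0.616, 0.502, 0.355, 0.502 and 0.616 in the order given. Without replicate 1 of the siANGPT1 libraries labelled LAMA84-R all 5 lists passed again (camera adjusted p = 1.68e-09, 0.000178, 0.0227, 0.0470 and 0.0154), and none with an estimated correlation (adjusted p = 0.0569, 0.351, 0.492, 0.492 and 0.696). In that setting 21 ATF4, 13 G1/S, 5 basophil and 10 erythroid genes fell. There 1 G1/S gene, 6 erythroid genes and 8 mitochondrial genes rose. That replicate 1 is not part of the comparison labelled K562R, so leaving it out changes mainly the shared spread. The median log2 fold change of the ATF4 list was -0.269 with it and -0.270 without it. That these lists passed again is therefore no independent support. By directional fry with all libraries, which does not compare a list with other genes, the ATF4 and mitochondrial lists did not pass (adjusted p = 0.272 and 0.0769). Both passed by mixed fry (adjusted p = 0.0464 and 0.00897), which takes changes in either direction and so gives no direction. The MYC target and ribosome biogenesis list missed the threshold (camera adjusted p = 0.0572) and passed without that replicate 1 (8 of 33 fell and 1 rose; camera adjusted p = 0.00523; adjusted p = 0.492 with an estimated correlation), as it did with all libraries and the size factors of DESeq2. Within this set, CANX lost its call without control replicate 2 or 3 or siANGPT1 replicate 1 (adjusted p up to 0.0665). NFE2 lost it without control 1 or 3 or siANGPT1 2 or 3 (up to 0.0841), and ND3 without any control or siANGPT1 1 or 3 (up to 0.0769). TPSAB1 and CHAF1A lost it without any 1 of the 6 libraries (up to 0.195 and 0.171). TPSAB1 also lost it without any control labelled LAMA84-R, and CHAF1A without control 1 or 3 or siANGPT1 3 there.

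Of 21 STAT5 target genes, 3 fell in the libraries labelled K562R and 18 did not pass (adjusted over the list alone, 6 fell). They were DUSP6, a phosphatase acting on ERK, which fell from 228.4 ± 11.4 to 150.1 ± 5.30 CPM (SD, n = 3 each), the anti-apoptotic gene MCL1 (-0.44) and the cytokine gene OSM (-0.63). The list missed the threshold (camera adjusted p = 0.0535; adjusted p = 0.355 with an estimated correlation), and without replicate 1 of the siANGPT1 libraries labelled LAMA84-R it passed (10 fell and 2 rose; camera adjusted p = 0.0274; adjusted p = 0.492 with an estimated correlation). With all libraries it passed by fry (adjusted p = 0.0155) and by camera with the size factors of DESeq2. Of 24 JAK/STAT components, 3 fell (adjusted over the list alone, 4 fell and 2 rose): CSF2RB (-0.92), the common beta chain of cytokine receptors, the phosphatase gene PTPN11 (-0.49) and IL4R (-0.54). The JAK/STAT list did not pass (camera adjusted p = 0.147; adjusted p = 0.616 with an estimated correlation). JAK2 (0.15, adjusted p = 0.601), STAT5A (-0.14, adjusted p = 0.700), STAT5B (0.24, adjusted p = 0.546), CISH (-0.24, adjusted p = 0.584), SOCS2 (0.35, adjusted p = 0.270), PIM1 (-0.19, adjusted p = 0.796), BCL2L1 (-0.17, adjusted p = 0.0947) and MYC (-0.02, adjusted p = 0.965) did not pass. Without that replicate 1, STAT5A (-0.15, adjusted p = 0.0291), CISH (-0.24, adjusted p = 0.0363), PIM1 (-0.19, adjusted p = 0.00388) and BCL2L1 (-0.18, adjusted p = 0.0115) passed as lower, and STAT5B (0.24, adjusted p = 0.00290) and SOCS2 (0.34, adjusted p = 0.000754) as higher, and these 6 also passed with only the 6 libraries labelled K562R. Of 9 angiopoietin and TIE receptor genes, the integrin gene ITGB1 rose (0.38), and ANGPT1 and PTPRB (-0.74), a phosphatase that acts on TEK, fell (adjusted over the list alone, the same counts). The median (0.28) and mean (0.15) of that list were positive and its test pointed down (camera adjusted p = 0.504). The receptor genes TEK (4.72 and 5.71 CPM with empty vector and siANGPT1) and TIE1 (10.2 and 10.7 CPM) did not pass with or without that replicate 1. Of 26 BCR-ABL1 signalling genes, 1 fell (adjusted over the list alone, 1), the kinase gene SRC, from 30.3 ± 1.56 to 12.6 ± 1.57 CPM (SD, n = 3 each). Of 14 drug transporter and TKI resistance genes, the efflux transporter gene ABCC4 fell (-0.30) and IGF1R rose (0.31) (adjusted over the list alone, 2 fell and 2 rose). The BCR-ABL1 signalling and drug transporter lists did not pass (camera adjusted p = 0.118 and 0.307). Leaving out any 1 of the 6 libraries labelled K562R ended the calls of OSM, IL4R and IGF1R (adjusted p up to 0.205, 0.171 and 0.191). So did leaving out control 1 labelled LAMA84-R, and for OSM and IGF1R also control 3, and for IGF1R siANGPT1 2 or 3 there. Within the set labelled K562R, ABCC4 lost its call without control 1 or 3 or siANGPT1 1 (up to 0.0577), PTPRB without any control or siANGPT1 1 or 3 (up to 0.0755) and ITGB1 without any control or siANGPT1 2 or 3 (up to 0.0918). Without replicate 1 of the siANGPT1 libraries labelled LAMA84-R 7 JAK/STAT components fell and 3 rose, 3 BCR-ABL1 signalling genes fell, and 2 drug transporter genes fell and 2 rose.

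In the libraries labelled LAMA84-R, TBC1D4, a regulator of glucose transporter traffic, rose from 0.332 ± 0.237 to 11.9 ± 4.34 CPM, and the fatty acid receptor gene CD36 rose from 14.0 ± 1.09 to 103.5 ± 36.1 CPM (SD, n = 3 each). MYEF2 rose again (2.68), with the transcription factor gene CREB5 (2.63) and BIRC3 (2.14), an inhibitor of apoptosis. ABCB1, the drug efflux pump P-glycoprotein, rose from 41.8 ± 3.49 to 101.5 ± 14.7 CPM (SD, n = 3 each; edgeR adjusted p = 4.70e-05) and was at 54.7 and 54.4 CPM in the 2 groups labelled K562R. It was the 1 gene of 14 in the drug transporter and TKI resistance list to pass (adjusted over the list alone, 1). PLPP4 fell from 10.3 ± 1.14 to 1.90 ± 0.115 CPM, and EDNRB, an endothelin receptor gene, fell from 21.8 ± 1.15 to 9.97 ± 2.59 CPM (SD, n = 3 each). ZDHHC15 (-2.12), the protease gene PRSS23 (-1.40), MLLT3 (-1.02) and CLU (-0.95), a secreted chaperone, fell as well. ERO1B, CACNA1I, CCDC141, LYST and SLC4A1 rose with log2 fold changes of 1.78 to 1.95, and IL18RAP, CNIH3, CPNE5 and CD96 fell with log2 fold changes of -1.28 to -0.85. Of the 20 genes other than ABCB1, 12 passed whichever library was left out. With only the 6 libraries of this set 5 of the 20 did, TBC1D4, CD36, SLC4A1, PLPP4 and ZDHHC15 (the other 15 at an adjusted p of 0.0773 to 0.359). BIRC3, EDNRB, CPNE5, CNIH3, ERO1B, CCDC141 and IL18RAP failed without any 1 of the 3 controls labelled LAMA84-R, and SLC4A1 without control 1 or 2 (adjusted p up to 0.0506). ERO1B, CCDC141 and IL18RAP also failed without any 1 of the 6 libraries labelled K562R, and CNIH3 without control 1 or siANGPT1 3 among those. The adjusted p went up to 0.0734, 0.161, 0.103 and 0.147 for BIRC3, EDNRB, CPNE5 and CNIH3, and up to 0.153, 0.195 and 0.174 for ERO1B, CCDC141 and IL18RAP.

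In all, 169 genes were higher and 75 lower in the siANGPT1 libraries labelled LAMA84-R (edgeR, adjusted p under 0.05). Replicate 1 of these siANGPT1 libraries stood apart: it correlated at 0.969 and 0.971 with the other 2 of its group, which correlated at 0.993 with each other (log2 CPM across genes, which are not independent replicates). Without it 427 genes were higher and 414 lower, while with only the 6 libraries labelled LAMA84-R 8 were higher and 3 lower. Without replicate 1, 2 or 3 of its controls the total was 91, 100 and 82, without siANGPT1 replicate 2 or 3 it was 475 and 439, and without 1 of the controls labelled K562R 47 to 49 genes were lower. BIRC3 was at 14.5 CPM in replicate 1 and at 5.17 and 4.84 CPM in the other 2 siANGPT1 libraries, and CREB5 at 44.2 CPM against 15.8 and 17.2 CPM. Without replicate 1 BIRC3 was still higher (1.43, adjusted p = 3.44e-05), as were CREB5 (1.98, adjusted p = 2.87e-08) and ABCB1 (1.15, adjusted p = 3.05e-09).

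**Figure D2:**
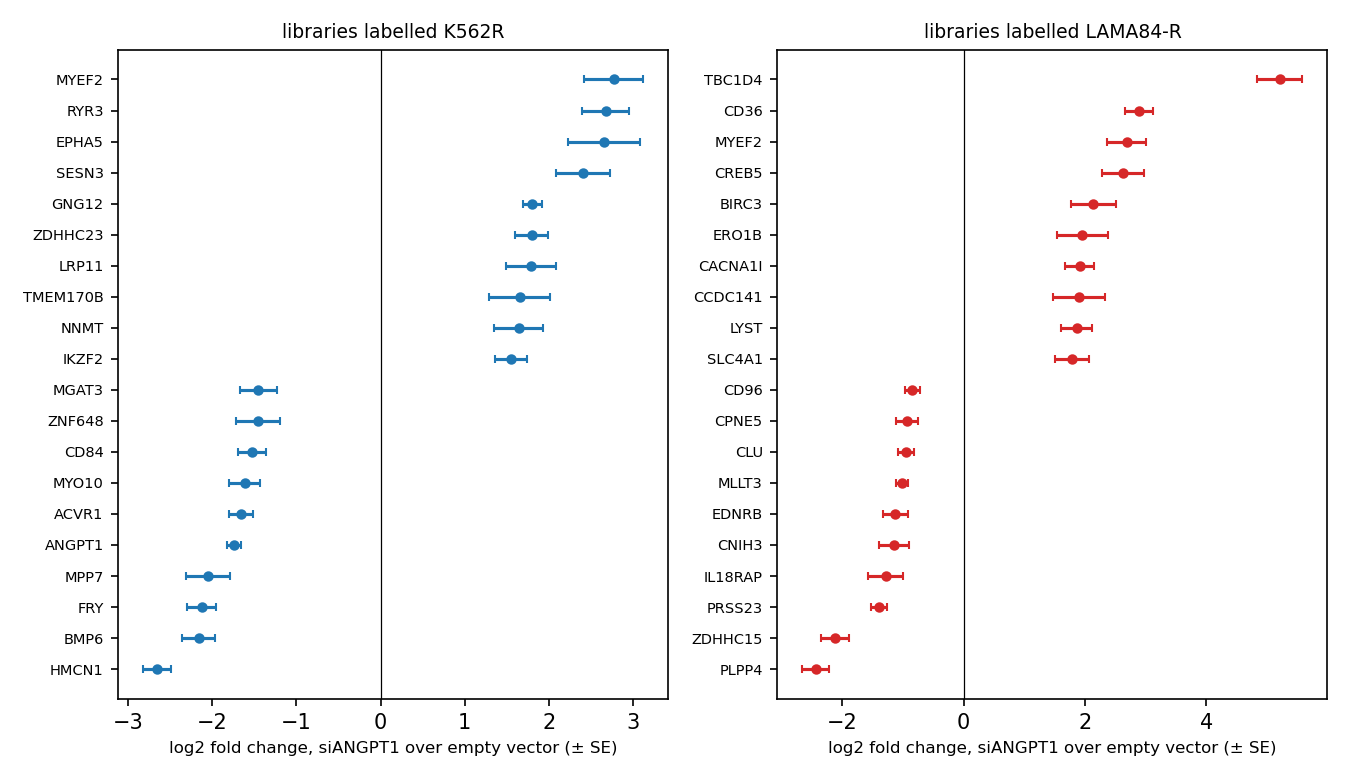
Log2 fold change (± SE) of siANGPT1 over empty vector for the 10 genes with the largest rise and the 10 with the largest fall under the rule fixed in advance, in each set of 6 libraries. MYEF2 is among the rising genes of both sets, at 2.77 and 2.68.

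Replicate 1 of the siANGPT1 libraries labelled LAMA84-R carried high counts of ATF4 target genes. ATF3 had 4307 counts in it and 219 and 277 in the other 2 siANGPT1 libraries. ASNS, asparagine synthetase, had 24823 counts against 4953 and 4290, and TXNIP had 534 against 3814 and 3153. Over all 3 siANGPT1 libraries 0 of 38 ATF4 and unfolded protein response genes passed with edgeR (adjusted over the list alone, 0; camera adjusted p = 0.568). At an unadjusted p under 0.05, 9 were higher and 2 lower, DESeq2 called 1 lower and limma voom 0. Without replicate 1, a setting for lists chosen after seeing the data, 9 fell (camera adjusted p = 3.09e-08; adjusted p = 0.0841 with an estimated correlation). In the libraries labelled K562R the same setting gave 21 that fell (camera adjusted p = 1.68e-09; adjusted p = 0.0569 with an estimated correlation).

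**Figure D3:**
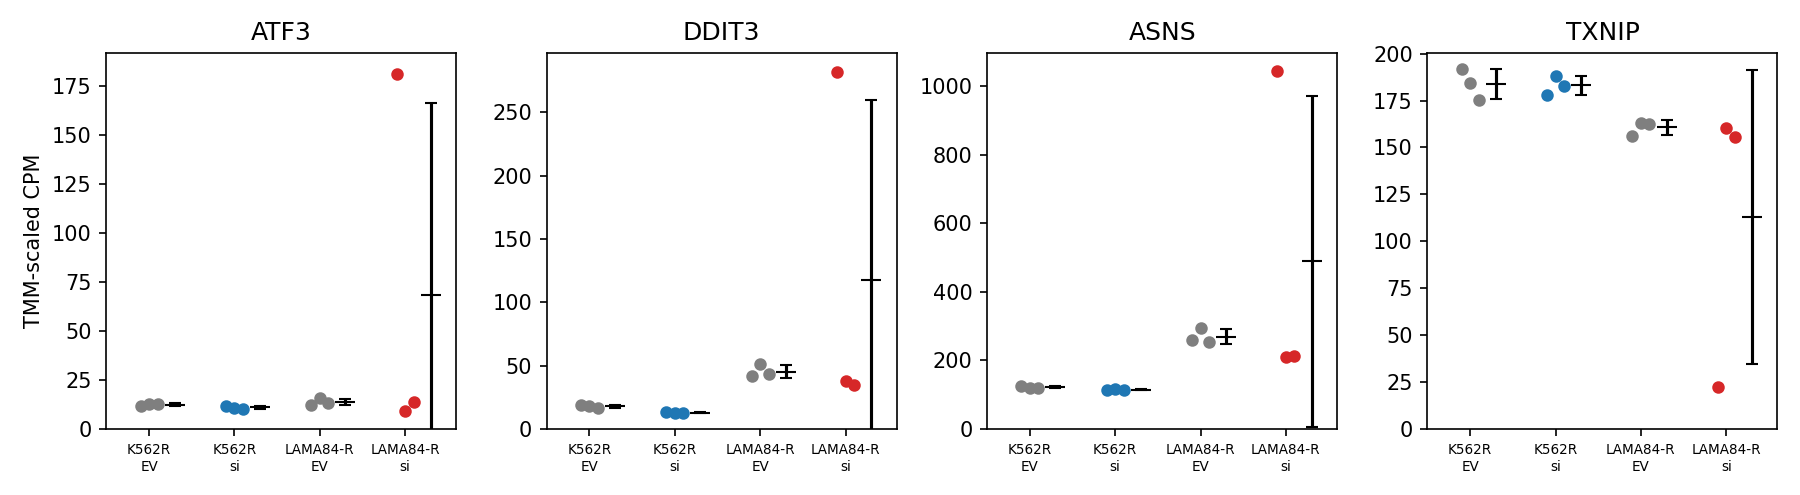
TMM-scaled CPM of ATF3, DDIT3, ASNS and TXNIP in each library (points, left to right replicates 1 to 3), with the mean and SD of each group of 3 (bars; the axis starts at 0, below which some SD bars would run). In replicate 1 of the siANGPT1 libraries labelled LAMA84-R, ATF3, DDIT3 and ASNS lie above and TXNIP below all the other libraries, with ATF3 at 181.3 CPM and TXNIP at 22.5 CPM.

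Of 30 erythroid genes, 3 rose in the libraries labelled LAMA84-R (adjusted over the list alone, 6 rose and 1 fell): the anion exchanger gene SLC4A1 (1.78), TFRC (0.51) and HBG2 (0.39), which is uncertain because HBG1 can share its reads. The STAT5 target gene SOCS3 rose (0.87), 1 of 21 (adjusted over the list alone, 3 rose and 1 fell), and so did the JAK/STAT component CSF2RB (1.72), 1 of 24 (adjusted over the list alone, 1), from 0.282 to 0.952 CPM. PTPRB rose (0.83), 1 of 9 angiopoietin and TIE receptor genes (adjusted over the list alone, 1 rose and 2 fell). The kinase gene FYN (-0.37) and the adaptor gene DOK2 (-0.45) fell, 2 of 26 BCR-ABL1 signalling genes (adjusted over the list alone, 2). In this set the STAT5 target and JAK/STAT lists did not pass (camera adjusted p = 0.885 and 0.607). Nor did the angiopoietin and BCR-ABL1 lists (camera adjusted p = 0.693 for each). TFRC, SOCS3, FYN and DOK2 lost their calls without any 1 of the 3 controls labelled LAMA84-R, HBG2 without control 1 or 3 and PTPRB without control 1 or 2. SOCS3 and DOK2 also lost theirs without any 1 of the libraries labelled K562R, FYN without any control among those, and FYN and DOK2 without siANGPT1 2 labelled LAMA84-R. The adjusted p went up to 0.102, 0.161, 0.130, 0.165, 0.126 and 0.0801 for TFRC, SOCS3, FYN, DOK2, HBG2 and PTPRB. PIM1, another STAT5 target gene, was at 1229 CPM in replicate 1 and at 439.3 and 423.2 CPM in the other 2 siANGPT1 libraries (adjusted p = 0.0889), and JAK2, STAT5A, STAT5B, TEK, TIE1, CISH, SOCS2, BCL2L1 and MYC did not pass by edgeR with all 12 libraries and the filter. Without replicate 1 PIM1 (0.43, adjusted p = 1.50e-05) and STAT5A (0.23, adjusted p = 0.00784) passed as higher and BCL2L1 (-0.21, adjusted p = 0.0161) as lower. PIM1 also passed as higher without siANGPT1 replicate 2 (1.37) or 3 (1.38). Those fits keep replicate 1 and its high value, so they do not bear on the smaller rise of 0.43 seen without it. With no filter on low counts PIM1 (1.15), STAT5B (0.49) and CISH (0.45) passed as higher, and with DESeq2 BCL2L1 (-0.20) as lower. Without replicate 1, 5 erythroid genes rose and 1 fell. Of STAT5 target genes and JAK/STAT components 2 each rose and 1 each fell, and 1 angiopoietin and TIE receptor gene rose and 2 fell. Hypoxia response genes leaned higher (median log2 fold change 0.45, camera adjusted p = 0.0119) and G2/M mitosis genes too (0.15, camera adjusted p = 0.0210), with 0 of 21 and 0 of 34 called by edgeR (adjusted over the list alone, 2 rose and 1 fell, and 4 rose). At an unadjusted p under 0.05, 12 of the hypoxia genes were higher and 1 lower, and 11 of the G2/M genes were higher and 1 lower. DESeq2 called 1 hypoxia gene higher and 1 lower and 4 G2/M genes higher, and limma voom 1 hypoxia gene lower and 0 G2/M genes. Without replicate 1 the adjusted p of these lists was 0.665 and 0.843. Cholesterol synthesis genes leaned lower (-0.12, camera adjusted p = 0.0210), as did mitochondrially encoded genes (-0.15, camera adjusted p = 0.0202), with 0 of 27 and 0 of 13 called by edgeR (adjusted over the list alone, 1 fell and 0). At an unadjusted p under 0.05, 7 and 4 were lower, and DESeq2 and limma voom each called 1 cholesterol gene lower and 0 mitochondrial genes. Without replicate 1 their adjusted p was 0.00390, with 3 of 27 lower, and 0.0527 (adjusted p = 0.542 and 0.809 with an estimated correlation). None of these 4 list calls held with an estimated correlation, where the adjusted p was 0.864, 0.864, 0.568 and 0.686, and by fry the hypoxia, G2/M and mitochondrial lists did not pass (adjusted p = 0.355, 0.405 and 0.149). Lists that camera did not call with all libraries passed without replicate 1: basophil and mast cell genes as higher (4 of 11; camera adjusted p = 0.0378) and megakaryocyte and platelet genes (3 of 17; 0.0289), granulocyte and monocyte genes (2 of 14; 0.00697) and ribosomal protein genes (0 of 39; 0.0497) as lower. With an estimated correlation these 4 had an adjusted p = 0.542, 0.542, 0.360 and 0.863. With all libraries the median of the ribosomal protein list changed sign with the scaling.

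Some genes moved alike in both sets. MYEF2, the apelin receptor gene APLNR (1.06 and 1.76), PDK2 (0.83 and 1.09), a kinase of the pyruvate dehydrogenase complex, the spectrin gene SPTB (0.48 and 0.67) and FZD3 (0.52 and 0.43) were among 19 genes higher in both, where independent lists would share 5.26 (Fisher's exact test, adjusted p = 2.68e-06). The galectin gene LGALS1 fell from 74.0 to 44.9 CPM in the libraries labelled K562R and from 335 to 202.1 CPM in the others. PRSS23, the cathepsin gene CTSS, SH3BGRL3 and CMIP were also among the 12 genes lower in both, against 1.91 for independent lists (Fisher's exact test, adjusted p = 1.59e-06). TFRC, CSF2RB and PTPRB were among 9 genes lower in the libraries labelled K562R and higher in the others, against 4.31 (Fisher's exact test, adjusted p = 0.0559). AQP1, CLU, CREB3L1, GALC and PTMS were the 5 genes higher in the libraries labelled K562R and lower in the others, against 2.33 (Fisher's exact test, adjusted p = 0.0840). Fisher's test takes genes as independent. Both comparisons also share one gene-wise spread, so genes of small spread can pass in both whatever the response. The opposite directions lay above the counts for independent lists too, so the p-values of these overlaps do not by themselves show a shared response. Leaving out 1 of the 6 libraries labelled K562R gave 4 to 9 genes higher in both, leaving out 1 of the controls labelled LAMA84-R gave 7 to 11 higher and 6 to 7 lower, and leaving out siANGPT1 replicate 2 or 3 labelled LAMA84-R gave 30 higher each time, with 20 lower for replicate 3. In the set labelled K562R, APLNR lost its call without control 1 (adjusted p = 0.0556), PDK2 without any control or siANGPT1 1 (up to 0.0798) and SPTB without any 1 of the 6 libraries (up to 0.125). In the set labelled LAMA84-R, PDK2 and CMIP lost theirs without control 1 or 3 (up to 0.0608 and 0.0638). FZD3 lost it without any control of either set, siANGPT1 3 labelled K562R or siANGPT1 2 labelled LAMA84-R (up to 0.136), and CTSS lost it in both sets without any control of either set or any siANGPT1 library labelled K562R (up to 0.169 and 0.155). Across all 15591 genes, which are not independent replicates, the log2 fold changes of the 2 sets correlated weakly (Pearson r = 0.0571, Spearman rho = 0.130). Among 10617 genes with a mean of at least 5 CPM rho was 0.209, and among the 883 genes called in the libraries labelled K562R it was 0.279, with 567 (64.2%) of one sign in both sets. Among the 244 called in the libraries labelled LAMA84-R it was 0.159, with 135 (55.3%) of one sign. A called gene with a log2 fold change of 0 in the other set was scored as not of one sign. Without replicate 1 of the siANGPT1 libraries labelled LAMA84-R r was 0.00276 and rho 0.0311 over all genes, and the genes then called in the libraries labelled K562R and LAMA84-R had a rho of 0.117 and 0.0797, with 54.4% and 53.6% of one sign. There were then 96 genes higher and 90 lower in both, against 43.7 and 43.5 for independent lists (Fisher's exact test, adjusted p = 2.63e-13 and 3.38e-11). The opposite directions, which did not pass with all libraries, passed too, with 55 genes higher in the libraries labelled K562R and lower in the others, against 42.3, and 67 the other way round, against 44.8 (Fisher's exact test, adjusted p = 0.0400 and 0.000991).

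**Figure D4:**
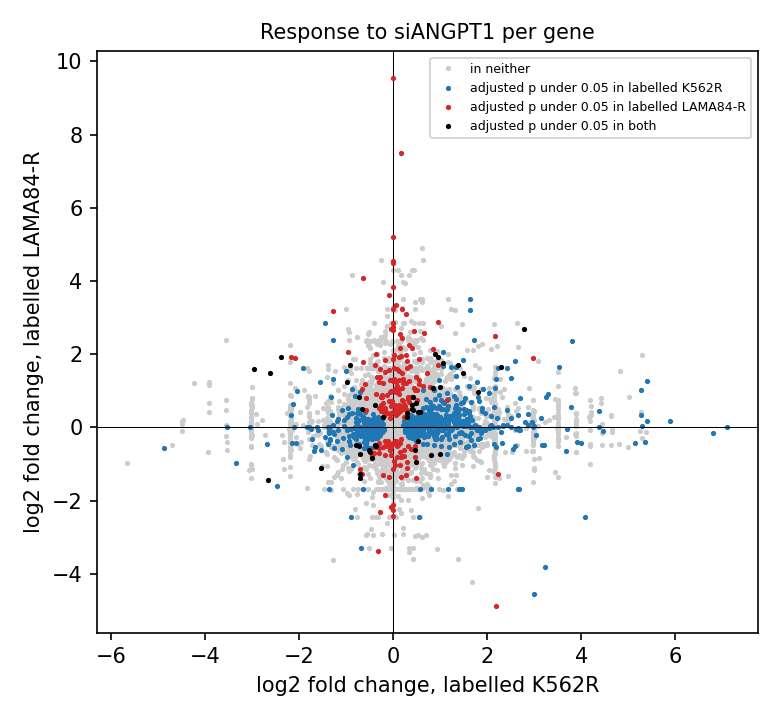
Log2 fold change of siANGPT1 over empty vector for each of the 15591 genes tested, in the libraries labelled K562R (x axis) and labelled LAMA84-R (y axis), coloured by where the adjusted p was under 0.05. The points show little common slope (Pearson r = 0.0571).

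The difference of the 2 responses was tested directly. The response of TCAM1P, ANTXR1, PPM1E, IL13RA1 and PREX1 was the more positive in the libraries labelled K562R, where ANTXR1 was at 0.0559 CPM with empty vector and 1.26 CPM with siANGPT1, against 33.8 and 31.5 CPM in the other set. All 5 averaged no more than 1.64 CPM in either group labelled K562R and passed the minimum of 5 CPM through the other set. The response of POF1B, TBC1D4, TMEM100, CCDC141 and MAGI1 was the more negative in the libraries labelled K562R: MAGI1 was at 122.5 and 140 CPM in them, and at 0.473 and 4.64 CPM in those labelled LAMA84-R. POF1B, TBC1D4 and TMEM100 likewise averaged no more than 0.332 CPM in the controls labelled LAMA84-R. TFRC (-1.18, adjusted p = 0.000798), CSF2RB (-2.64, adjusted p = 0.000137), KIT (-1.15, adjusted p = 0.00814) and ABCB1 (-1.29, adjusted p = 0.000675) also differed, by edgeR. Of 30 erythroid genes 6 had the more negative response in the libraries labelled K562R (adjusted over the list alone, 9; camera adjusted p = 0.00163), among them SLC4A1, TFRC and RHAG. So did 2 of 11 basophil and mast cell genes, KIT and FCER1A (adjusted over the list alone, 4; camera adjusted p = 0.000636), and 2 of 38 ATF4 and unfolded protein response genes, SDF2L1 and CALR (adjusted over the list alone, 8; camera adjusted p = 0.000155). The response was the more positive there for ND3, 1 of 13 mitochondrially encoded genes (adjusted over the list alone, 8; camera adjusted p = 0.000155), for THBS1 and CLU, 2 of 17 megakaryocyte and platelet genes (adjusted over the list alone, 4; camera adjusted p = 0.0238), and for IDI1, 1 of 27 cholesterol synthesis genes (adjusted over the list alone, 3; camera adjusted p = 0.0243). With an estimated correlation the adjusted p of these 6 lists was 0.312, 0.101, 0.706, 0.312, 0.312 and 0.312, and by fry the ATF4 list did not pass (adjusted p = 0.316). Without replicate 1 of the siANGPT1 libraries labelled LAMA84-R the ATF4 list lost its call (camera adjusted p = 0.153) and the other 5 passed (0.0161, 0.00131, 0.00153, 0.0161 and 0.00797), though none of the 6 with an estimated correlation (adjusted p = 0.454 for ATF4 and 0.385 for the others). In that setting 8 erythroid, 5 basophil and 11 ATF4 genes were more negative. There were 3 erythroid, 4 ATF4, 5 mitochondrial, 4 megakaryocyte and 8 cholesterol synthesis genes more positive. STAT5 target genes (0.0161), G1/S replication genes (0.0161) and MYC target and ribosome biogenesis genes (0.000822) passed as more negative without that replicate 1 and not with all libraries, each with an adjusted p = 0.385 with an estimated correlation. With all libraries the median of the MYC target list changed sign with the scaling. In all 154 genes had the more positive and 168 the more negative response in the libraries labelled K562R (edgeR). Scaled by library size alone these were 241 and 135, and without that replicate 1 they were 893 and 900. Leaving out any 1 of the 6 libraries labelled K562R gave 144 to 167 in all, and leaving out 1 of the controls labelled LAMA84-R gave 163 to 244. Without any 1 of the controls labelled K562R, TCAM1P (adjusted p up to 0.0591), PPM1E (up to 0.0591) and POF1B lost the call, and PREX1 (up to 0.120) and CCDC141 (up to 0.0758) did without control 2 or 3. POF1B, PREX1 and CCDC141 also lost it without any siANGPT1 library labelled K562R, and TCAM1P without siANGPT1 1 or 2. Without any 1 of the controls labelled LAMA84-R it was lost by POF1B (up to 0.0705), TMEM100 (up to 0.0689), PREX1 and CCDC141, and TMEM100 lost it without control 1 labelled K562R.

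With empty vector alone, the 2 sets were far apart. In this design the line and any batch of preparation cannot be told apart, here or in the difference of responses. SLFN11, a gene that sensitises cells to DNA damage, was at 215.6 ± 3.71 CPM (SD, n = 3) in the libraries labelled K562R and at 0 in the others, at least 1510-fold higher against a floor of 3 counts per library. HMGA2, a chromatin protein gene, was at 929 ± 44.4 CPM (SD, n = 3) in the libraries labelled LAMA84-R and at 0 in the others, at least 4056-fold higher by the same floor. LXN, PIEZO2, ROBO2, SIGLEC12, MTAP, CLVS2 and VAV3 were likewise at 0 in the controls labelled LAMA84-R, while TIMP3 and PHLDB2 had 1 and 2 counts there over 3 libraries. KIF1A, MEG3, KRT19, CDCP1, DLK1, COCH, DPCR1, PAWR and TNFRSF1B were at 0 in the controls labelled K562R. Of 11 basophil and mast cell genes, 10 were higher in the libraries labelled K562R (adjusted over the list alone, 10; camera adjusted p = 6.86e-05), among them the histidine decarboxylase gene HDC (703.9 and 0.122 CPM) and KIT (837 and 111.1 CPM), and this list also passed with an estimated correlation (adjusted p = 0.0452), though not without replicate 1 of the siANGPT1 libraries labelled LAMA84-R (adjusted p = 0.123). Of 39 ribosomal protein genes, 35 were higher there (adjusted over the list alone, 35; camera adjusted p = 7.56e-09; adjusted p = 0.771 with an estimated correlation). Of 17 megakaryocyte and platelet genes, 12 were higher and 3 lower (adjusted over the list alone, the same counts; camera adjusted p = 0.00445; adjusted p = 0.430 with an estimated correlation), and of 27 interferon response genes 17 and 7 (adjusted over the list alone, the same counts; camera adjusted p = 0.00445; adjusted p = 0.307 with an estimated correlation). Of 15 replication-dependent histone genes, 13 were lower (adjusted over the list alone, 13; camera adjusted p = 0.00561; adjusted p = 0.430 with an estimated correlation). In all 4998 genes were higher and 6142 lower in the controls labelled K562R (edgeR, adjusted p under 0.05), with a median log2 fold change over all genes of -0.11, which was -0.32 when scaled by library size alone.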

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

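The tests of the lowest MTAP count, of cells of the other set, of depth, of the stress gene list, of the correlation without replicate 1, of noise among genes of at least 5 CPM, of the interval of the ANGPT1 ratio and of a response scaled down as a whole were chosen only after the result was seen.

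The responses to siANGPT1 differed between the 2 sets by a direct test of the difference, with 154 genes more positive and 168 more negative in the libraries labelled K562R (edgeR, adjusted p under 0.05). Of the named genes, the difference in log2 fold change was 6.94 for TCAM1P, 4.56 for ANTXR1, 3.94 for PPM1E, 3.65 for IL13RA1, 2.67 for PREX1, 2.12 for GNG12, 1.99 for NNMT, 1.43 for CLU, 1.34 for IKZF2, 1.15 for MLLT3, 1.12 for EGR1, 0.97 for THBS1, 0.61 for ND3 and 0.60 for IFITM3. It was negative for POF1B (-7.32), TBC1D4 (-5.23), TMEM100 (-4.73), CACNA1I (-4.31), CCDC141 (-3.99), MPP7 (-3.06), MAGI1 (-3.05), FRY (-2.78), CSF2RB (-2.64), SLC4A1 (-2.44), CREB5 (-2.19), FCER1A (-2.16), CD36 (-1.94), PTPRB (-1.56), ANGPT1 (-1.41) and NR4A2 (-1.41). Smaller negative differences were those of ABCB1 (-1.29), HMCN1 (-1.22), MGAT3 (-1.20), TFRC (-1.18), KIT (-1.15), ACVR1 (-1.12), SOCS3 (-1.11), SRC (-1.07), CALR (-0.88), SDF2L1 (-0.60), SDHD (-0.59), PTPN11 (-0.57), HBG2 (-0.52), MCM6 (-0.51), MDM2 (-0.45), RHAG (-0.41) and MCM3 (-0.35). The values of TCAM1P (0 counts in the controls labelled K562R and 32 in the siANGPT1 libraries there) and POF1B (0 counts in the controls labelled LAMA84-R) are fitted over a group at 0 and measure no size, and those of ANTXR1, PPM1E and TMEM100 rest on a group with 1 or 2 counts. Those of IL13RA1 and PREX1 rest on 7 and 4 counts over the controls labelled K562R, so their sizes are uncertain too. Of 100 drawn splits of the libraries into arms, 2 gave as many genes, the real one with 322 and 1 with 902, which exchanged the arms of the set labelled LAMA84-R and so adds the 2 responses in place of subtracting them. The share, under 0.05, excludes only that a random choice of arms within the sets gives as many genes. It does not test a difference between the responses, since most splits remove the response of a set: the other splits that kept the arms labelled K562R gave 48 to 207 genes and those that did not gave 0 to 17.

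For the other comparisons 6 libraries give 10 splits, too few for a share under 0.05. In each, 1 of the 10 gave as many genes, the real one. It had 883 genes in the libraries labelled K562R (highest other 0), 244 in those labelled LAMA84-R (highest other 1) and 11140 between the empty vector sets (highest other 0).

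MTAP, deleted in the K562 line, was at 0 in the 6 libraries labelled LAMA84-R and present in those labelled K562R, whose short names begin with LR. Right line names with a loss of MTAP in LAMA84-R are argued against by the lowest MTAP count in the libraries labelled K562R, 1203, where a deletion leaves no reads. HLA-B (0 against 47 to 169 counts) and HLA-C (164 to 274 against 0 to 5 counts) went opposite ways between the sets, and RPS18 and TAP1 of the same region had 0 counts in all 12 libraries, so that region settles nothing. In the controls labelled K562R and LAMA84-R the embryonic globin genes HBE1 (9.53 and 967 CPM) and HBZ (1.22 and 72.3 CPM), which K562 is known to express, point towards an exchange of the line names, as MTAP does. CDKN2A (0 or 1 against 2 to 24 counts) points away from it, but was at no more than 1.01 CPM in any library. At such levels a count of 0 or 1 does not tell a deletion from a nearly silent gene. CDKN2B (0 to 2 against 1 to 7 counts) was also near the floor. The fetal globin genes HBG1 (41.1 and 187.3 CPM) and HBG2 (1905 and 599.9 CPM), which can share reads, went opposite ways. An exchange, libraries of another origin and the patient cells of the design text stay open.

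Replicate 1 of the siANGPT1 libraries labelled LAMA84-R lay more than 2-fold above the median of the other 5 of its set in 730 genes and below it in 481, against at most 99 and 81 for any other library, and it set apart the first principal component of that set (55.0% of the variance). Lower depth is argued against by its total count, 1.08 times the median of the other 5, and cells of the other set by MTAP, of which 3 counts would stand for a share of 0.139% and it had 0. An untransduced or unrelated culture in its place is argued against by 113 genes changed in replicates 2 and 3, of which 88.5% went the same way in replicate 1 (exact 95% interval 81.1% to 93.7%). That interval treats genes as independent and is likely too narrow. A stress response in that culture may account for part of the difference: the ATF4 and unfolded protein response list lay higher in it by a median log2 difference of 0.87 (32 of 38 genes above 0), above the upper end of the central 95% of 10000 lists matched on expression, 0.15. It was seen and tested on the same data, and what set it off was not tested.

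The responses of the 2 sets correlated weakly across genes (Pearson r = 0.0571, Spearman rho = 0.130), with rho = 0.279 among the 883 genes called in the libraries labelled K562R and 0.159 among the 244 called in the others (0.117 and 0.0797 among the genes called without replicate 1). Noise that hides a strong shared response is argued against by the correlation corrected for error variance, 0.108 (95% bootstrap interval 0.0681 to 0.148), and 0.160 (0.120 to 0.204) among genes of at least 5 CPM. The bootstrap and exact intervals in this paragraph treat genes as independent and hold no spread between libraries, so they are likely too narrow. Replicate 1 is argued against as the reason, since r was 0.00276 without it, and rho 0.0765 among genes of at least 5 CPM. A response that is as a whole a scaled-down copy of the other is argued against by the 55.3% of those 244 genes with one sign in both sets (exact 95% interval 48.9% to 61.7%) and by the low corrected correlations, which scaling would not lower. Of the 187 of them with a mean of at least 5 CPM in the libraries labelled K562R, 114 had one sign (61.0%, exact 95% interval 53.6% to 68.0%). Over the 883 genes the slope was 0.0600 (95% bootstrap interval 0.0136 to 0.109), above 0 and below the ratio for ANGPT1 itself, 0.189. The 95% interval of that ratio starts at 0.0790, so a parallel part in proportion to the smaller fall of ANGPT1 stays open. A difference between the lines as the cause stays open too, since the direct test shows that the responses differed and not why. Effects of the construct other than the loss of ANGPT1 were not tested and stay open as well.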

How the results depend on the processing

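The list tests and the counts of list members without replicate 1 of the siANGPT1 libraries labelled LAMA84-R were tests chosen only after the result was seen, and the other settings were planned.

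ANGPT1 was lower with siANGPT1 in both sets under every setting run. Leaving out each library in turn gave log2 fold changes of -1.78 to -1.70 in the libraries labelled K562R and -0.42 to -0.27 in those labelled LAMA84-R, where it passed with DESeq2 (-0.32) and without siANGPT1 replicate 1 or 2. The same leaving out gave 198 to 1624 genes higher and 175 to 1668 lower in the libraries labelled K562R, 58 to 427 and 24 to 414 in those labelled LAMA84-R, 63 to 893 and 80 to 900 for the difference of responses, 4705 to 5761 and 5777 to 6815 between the empty vector sets, and 4 to 96 and 6 to 90 changed alike in both sets. The correlation across genes ran from 0.00276 to 0.0769. The highest counts all came without replicate 1 of the siANGPT1 libraries labelled LAMA84-R, and a fit without a library rests on fewer samples.

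With DESeq2, 680 genes were lower in the libraries labelled K562R, 454 were higher and 242 lower in those labelled LAMA84-R, 331 and 432 differed in response, and 50 and 43 changed alike (correlation 0.0207). With no filter on low counts there were 1120 and 339 in the libraries labelled LAMA84-R, 317 and 542 for the difference, and 132 and 47 alike (correlation 0.0154). Limma voom gave 134 genes lower in the libraries labelled LAMA84-R (correlation 0.0773), and scaling by library size alone 241 more positive responses. With only the 6 libraries of a set there were 1919 and 2080 genes for the set labelled K562R and 8 and 3 for the other. For these settings the cause was not tested. A minimum absolute log2 fold change of 1 leaves fewer genes by construction: 215 and 56, 97 and 24, 94 and 68, 2658 and 3951 for the 4 comparisons in the order above, and 5 and 2 alike.

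With the replicate block, 247 genes were higher and 216 lower in the libraries labelled K562R, 95 and 33 in those labelled LAMA84-R, 56 and 69 differed in response and 9 were higher in both. Deviations of libraries with the same number correlated at -0.0464 to 0.0239 and not every library correlated best with its own number, so the numbers are not treated as pairs. The block ended the list calls of cholesterol synthesis genes and added 1 for MYC target genes in the libraries labelled K562R.

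Of 167 results for single named genes none changed sign with a call. Calls were lost for 2 with the size factors of DESeq2, 8 with library size alone, 17 with limma voom, 12 with no filter and 42 with the block, and gained for 2 with DESeq2 and 3 with no filter. With a set alone, 6 were gained for the set labelled K562R and 37 lost for the other. Leaving out each library in turn left 1629 calls as they were, ended 364 and added 11. No list that camera called with all libraries changed the sign of its median with the scaling. Depth limits what a count of 0 can exclude: 3 counts stand for 0.126 to 0.251 CPM in a library.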

Other observations

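The tests of counts that jump between replicates and of genes found in the other set were chosen only after the result was seen, and the gene lists were fixed in advance.

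Immediate early genes went both ways in the libraries labelled K562R. EGR1 rose from 13.2 ± 1.84 to 27.2 ± 4.38 CPM and the nuclear receptor gene NR4A2 fell from 6.27 ± 0.354 to 2.75 ± 0.241 CPM (SD, n = 3 each). PHLDA1 rose and DUSP6 fell, so 2 of 28 rose and 2 fell (adjusted over the list alone, 2 and 3). The p53 negative regulator MDM2 fell from 167.9 ± 0.963 to 120.7 ± 3.50 CPM, with PLK3 (-0.53), 2 of 24 p53 target genes (adjusted over the list alone, 2). The growth factor genes TGFB1 (-0.40) and PDGFA (-1.30) fell while ITGB1 rose, of 26 angiogenesis and adhesion genes (adjusted over the list alone, 4 and 3). The respiratory chain genes SDHD (-0.53) and NDUFA9 (-0.35) fell, 2 of 34 (adjusted over the list alone, 2, with 1 that rose), and so did IRF1 (-0.70) and DDX60 (-0.53), 2 of 27 interferon response genes (adjusted over the list alone, 2). NFKBIA (-0.58) fell and SOD2 (0.28) rose among 20 NF-kB target genes (adjusted over the list alone, 1 and 1), and STIP1 (-0.20) fell and HSPA4L (0.57) rose among 17 heat shock genes (adjusted over the list alone, 2 and 1). SPI1 (-0.62), KIT and GAPDH (-0.29) were the single genes that fell among granulocyte, progenitor and glycolysis genes (adjusted over the list alone, 1, 2 and 2, with 1 granulocyte gene that rose), and CLU (0.49), ANKRD37 (1.33) and SC5D (0.26) the single genes that rose among megakaryocyte, hypoxia and cholesterol synthesis genes (adjusted over the list alone, 1, 4 and 2). None of these lists passed by camera. The counts depend on replicate 1 of the siANGPT1 libraries labelled LAMA84-R, without which 4 immediate early genes rose and 6 fell, 5 p53 target genes each way, 3 and 5 angiogenesis and adhesion genes, 3 and 3 respiratory chain genes, 5 and 3 interferon response genes, 4 and 2 NF-kB target genes, and 2 and 5 heat shock genes. In the same order there were 1 and 1 granulocyte, 0 and 4 progenitor, 4 and 6 glycolysis, 2 and 0 megakaryocyte, 9 and 3 hypoxia and 8 and 2 cholesterol synthesis genes. Without any 1 of the 6 libraries labelled K562R the calls of PDGFA, PHLDA1, PLK3, GAPDH, NDUFA9, SC5D, STIP1, SPI1, CLU, DDX60 and ANKRD37 were lost (adjusted p up to 0.196). Of these, PHLDA1, PLK3, SC5D, STIP1, SPI1, CLU and ANKRD37 also lost theirs without control 1 or 3 labelled LAMA84-R, and DDX60 without control 3. ANKRD37 lost its call without control 2 there as well, PLK3, SC5D, STIP1, SPI1, CLU and ANKRD37 without siANGPT1 3, and SC5D and STIP1 without siANGPT1 2. In the set labelled K562R, NFKBIA, HSPA4L and ITGB1 lost theirs without any control or siANGPT1 2 or 3 (up to 0.132, 0.117 and 0.0918), SOD2 without control 1 or 2 or siANGPT1 2 or 3 (up to 0.0878) and IRF1 without control 1 or siANGPT1 3 (up to 0.0829).

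In the libraries labelled LAMA84-R, the matrix glycoprotein gene THBS1 fell from 28.7 ± 1.71 to 16.4 ± 3.17 CPM (SD, n = 3 each), with CLU, 2 of 17 megakaryocyte and platelet genes (adjusted over the list alone, 4), and IFITM3, an antiviral membrane protein gene, fell from 51.9 ± 4.56 to 36.3 ± 1.18 CPM, 1 of 27 interferon response genes (adjusted over the list alone, 2, with 3 that rose). The eosinophil granule gene PRG2 (1.70) and CNRIP1 (1.06) rose, 2 of 11 basophil and mast cell genes (adjusted over the list alone, 4). The replication helicase gene MCM6 (0.32) rose, 1 of 33 G1/S replication genes (adjusted over the list alone, 1), BIRC3 and SOD2 (0.28) rose, 2 of 20 NF-kB target genes (adjusted over the list alone, 3), and the collagen chaperone gene SERPINH1 (-0.55) fell, 1 of 17 heat shock genes (adjusted over the list alone, 1). Without replicate 1 of these siANGPT1 libraries 3 megakaryocyte genes fell, 4 interferon response genes fell and 1 rose, 4 basophil genes rose, 1 G1/S gene rose and 3 fell, and 3 NF-kB target genes rose. PRG2, MCM6 and SOD2 lost their calls without any 1 of the controls of either set (adjusted p up to 0.148, 0.117 and 0.179). PRG2 and SOD2 also lost theirs without any siANGPT1 library labelled K562R, MCM6 without siANGPT1 3 of these, and SOD2 without siANGPT1 2 or 3 labelled LAMA84-R. BIRC3 lost its call without any control labelled LAMA84-R (up to 0.0734), CNRIP1 without control 3 labelled LAMA84-R (0.0623) and SERPINH1 without control 2 or 3 (up to 0.0533).

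Some counts jumped between replicates of a group. Genes with at least 200 counts in 1 library and 8 times fewer in another numbered 2 and 3 in the empty vector and siANGPT1 groups labelled K562R, and 2 and 19 in those labelled LAMA84-R, where replicate 1 was the library apart in 18 of the 19, CHAC1, ATF3, DDIT3 and SLC7A11 among them. SMARCB1, a chromatin remodelling gene, had 18, 478 and 16 counts in the controls labelled LAMA84-R and 503, 16 and 272 in the siANGPT1 libraries there. TRAPPC4 had up to 278 and down to 8 counts in the same controls, and TBCE up to 283 and down to 11 in the siANGPT1 libraries labelled K562R.

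Genes at no more than 0.5 CPM in the controls of a set and at least 10 CPM in those of the other numbered 331 in the libraries labelled K562R, where 13 rose and 3 fell with siANGPT1. The median gain of those 13 was 3.77% of the level in the other set, and that of all 331 was 0%. In the libraries labelled LAMA84-R there were 269, of which 9 rose, with median gains of 3.40% for those 9 and 0.0131% for all. Picked for low control values, these genes had little room to fall. Of all 15591 genes tested, 485 were called higher in the libraries labelled K562R and 169 in the others. The gains of the 13 and the 9 are those of genes already called as rising.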
